A study of Homo sapiens with 6 samples.

How the data were processed

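Poly(A)-selected RNA was measured by sequencing in HCT116 cells, a human colon cancer line, that express ENL fused to an auxin-inducible degron together with the plant F-box protein AtAFB2, which links auxin-bound degrons to a ubiquitin ligase. ENL, the product of MLLT1, is a reader of acetylated histones. The 6 libraries form 3 groups of 2 replicates: untreated control, IAA (the auxin indole-3-acetic acid, 3 h at a dose the labels write as 500 um, taken here as micromolar), and washout (the same IAA treatment, a PBS wash and 48 h in normal medium). RNA was extracted with Trizol, selected with oligo dT and copied from random hexamers per the labels. The strand that was read is not given in the sources used here, and neither is what a replicate number stands for. The p-values for single genes therefore measure only the spread between these samples.

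The deposited values are FPKM, 1 value per gene and library for 31628 genes. Per the submitters' processing notes the tools were HISAT, Bowtie2, HTSeq and edgeR on the hg19 genome. Their versions, roles and order, the gene annotation release and any filter are not given in the sources used here. The values carry no coordinates, so none are given.

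What the FPKM divides by was tested on the values. The most common ratio of low values between libraries was taken to give the ratio of the library totals. Low genes were then chosen as those whose values, scaled by it, were whole multiples of 1 step. This choice does not itself show that the ratio holds for all genes. With gene spans from GENCODE 29, a GRCh38 annotation used only for spans, gene types and names, 71.5% of 4423 low genes gave a common library total when the whole span, introns included, was the length. With the exon length 23.9% did, and where the span was over 2 times the exon length (2419 genes) the shares were 76.7% and 0.0%. FPKM of long genes are therefore low, so changes were compared between libraries within a gene, and the filter on FPKM removes long genes at read numbers where short genes pass. GENCODE 29 held 94.3% of the gene IDs. Whole reads were recovered by dividing each value by its step. Of 21707 genes above 0, 99.79% had whole reads in all libraries (tolerance 0.02 reads) and 45 had no solution. The span fixed the reads of 16867 genes, and 4210 were set to the nearest and 585 to the smallest whole solution, so for these whole reads were imposed. In simulated data the recovery returned the exact reads for 98.2% of 14788 genes with at least 10 reads, and for 89.2% of 3433 genes whose span did not match.

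The library totals from the steps were 16610000 and 16760000 reads in control, 16440000 and 16770000 with IAA, and 16710000 and 16650000 after washout. The recovered reads summed to between 104.73% and 105.12% of these totals, and the sources used here do not say why. Between 18474 and 18853 genes were above 0 per library. Replicates differed by more than read counting alone, with a chi-square per gene of 2.7, 2.98 and 3.32 in control, IAA and washout.

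Genes with a mean FPKM of at least 1 over the 6 libraries (8317 genes) were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trend in the prior variance, a mean per group, 3 residual degrees of freedom and 1.81 prior degrees of freedom. The adjusted p is Benjamini-Hochberg over the genes tested in a comparison, two-sided, and changed means an adjusted p under 0.05 with no fold limit. Of the tested genes 75.9% were protein coding. Pseudogenes and genes whose symbols are clone names or some small RNA names made up 19.6%. Log2 changes are on the log2(FPKM + 1) scale, which shrinks those of low genes, and folds are ratios of mean FPKM. Errors beside FPKM are SD over n = 2, and errors beside log2 changes are SE.

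Before the data were examined, 24 gene lists were written from general knowledge, together with the test, its settings and the alternatives. The lists hold ENL and its complexes, BET proteins and P-TEFb control, genes near super-enhancers of colon cancer cells, MYC targets of ribosome biogenesis, WNT targets, HOX and stem cell genes, immediate early genes, aryl hydrocarbon receptor targets, p53 targets, S phase, G2 and mitosis, cholesterol synthesis, hypoxia and glycolysis, the integrated stress response and unfolded proteins, heat shock, NF-kB, interferon-stimulated genes, YAP targets, intestinal differentiation, cytosolic ribosomal proteins, respiratory chain, mitochondrial genes, histones, and markers of fibroblasts, endothelium and blood. The 20 lists with at least 5 tested members were tested with limma's camera at its preset correlation of 0.01, adjusted over all lists and the 3 comparisons. At the preset correlation camera compares list members with the other genes. Its p-values then rest mainly on the spread across genes, and a small one need not mean agreement between libraries. Camera with an estimated correlation and fry, which tests the members alone, were alternatives. With an estimated correlation camera has only the 3 residual degrees of freedom and little power. No list passed with it, so its values cannot tell whether a list changed.

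Named genes follow a rule set at the same time: MLLT1 in every library, the 10 largest rises and 10 largest falls among changed genes whose groups do not overlap, up to 4 members of smallest p in each list past its test and in the lists on super-enhancers, MYC targets and BET proteins, and MYC, HEXIM1 and CYP1A1. With no changed gene in a direction, the 5 of smallest p are given as values. Genes without a symbol and pseudogenes were passed over. When genes were ranked, those with such clone or small RNA symbols, or with symbols listed more than once, were passed over too. Members named because a count was 5 or fewer, and not by this rule, were chosen after their values were seen. The rule named 91 genes, of which 20 overlap exons of another gene in GENCODE 29, 2 of them on the same strand.

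Simulated libraries checked the test. All simulated genes shared 1 dispersion (0.00183), taken from the spread within groups of genes with many reads. The measured genes need not share 1 dispersion, and more of them changed. The shares and false calls here are therefore only rough benchmarks. With 50 genes raised or lowered at each fold in IAA against control, 9 (18%) were called at 1.25-fold and 33 (66%) at 1.5-fold. At 2-fold and at 4-fold 45 (90%) were called. Besides these true calls there were 14 false calls among 8312 genes. The false calls were a larger share of all calls than the adjusted p threshold aims at. In washout against IAA 5, 32, 45 and 46 were called at these folds, with 6 false calls, a share below that threshold. Voom on simulated reads of IAA against control called 72%, 88%, 92% and 100% at these folds, with 8 false calls among 14759 genes. A list of 28 members lowered 1.25-fold had a camera adjusted p of 2.84e-24, and 0 of 100 random lists were called. The simulated genes varied independently, so this check cannot show how camera behaves when list members vary together.

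Alternatives changed the pseudocount, the filter on low values, the scaling (FPKM rescaled to TPM, median centring, quantile normalization), the prior variance, the libraries in the fit, a block for the replicate number and the fold limit, and left out each library in turn, where a lone library is assumed to vary like the others. Tests on recovered reads (limma's voom, or log2 of scaled reads with limma-trend, for genes with a mean of at least 10 reads, 14771 genes) and on protein-coding genes alone were chosen after seeing the data. Gene spans and plots used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.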

Results

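Transcript levels were measured in 6 RNA-seq libraries of HCT116 cells whose ENL carries a degron, 2 each from untreated control cells, cells given IAA for 3 h to degrade ENL, and cells cultured for 48 h after IAA was washed out. Library totals ran from 16440000 to 16770000 reads, and 8220 to 8406 genes per library reached an FPKM of 1. The IAA libraries lay apart from the other 4 on the first principal component, which held 41.7% of the variance, at 13.83 and 13.69 against -5.54 and -7.61 for control and -7.33 and -7.04 for washout. The second component, with 15.6%, held control at 5.19 and 7.43, washout at -8.14 and -4.24, and IAA at -4.99 and 4.74. Pearson's r across genes was 0.9926 between the control libraries, 0.9917 between the IAA libraries and 0.9914 between the washout libraries, and 0.9855 to 0.987 between control and IAA. Genes are not independent replicates in these values. Of 17 matched markers of fibroblasts, endothelium and blood 0 passed the filter of a mean FPKM of 1 (COL1A1 had 0.642), which genes of long span can miss at many reads. Intestinal differentiation genes (CA2, mean FPKM 2.77) and histone genes (HIST1H1C, mean FPKM 7.95) had 3 and 2 members above the filter and were not tested as lists. Mitochondrial genes were not analysed here.

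MLLT1 (ENSG00000130382.7), which encodes ENL, had an FPKM of 0.412 and 0.427 in control, 0.404 and 0.358 with IAA, and 0.413 and 0.384 after washout. These values lie below the filter of 1 and stand for 459 and 480, 445 and 402, and 463 and 428 reads. On recovered reads the MLLT1 log2 change was -0.14 in IAA against control (voom, adjusted p = 0.334), so no change in its mRNA was detected. The degron acts on the protein, which RNA does not measure.

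The comparison of IAA with control asked which transcripts change within 3 h of ENL degradation. It also asked whether genes listed as near super-enhancers are among them. F3, the tissue factor that starts coagulation, fell from 27 ± 1.19 to 7.04 ± 0.183 FPKM (SD, n = 2 per group, limma log2 change -1.80, SE 0.067, adjusted p = 0.00167). SOX4, a developmental transcription factor, fell from 50.1 ± 1.87 to 19.8 ± 0.387 FPKM (n = 2, limma adjusted p = 0.00167), and MYC (ENSG00000136997.10), a driver of cell growth, from 108 ± 2.69 to 61.7 ± 1.66 FPKM (log2 change -0.80, SE 0.04, limma adjusted p = 0.00297). The largest rise was that of CYP1A1 (ENSG00000140465.9), an enzyme that oxidises foreign compounds and a classic target of the aryl hydrocarbon receptor, from 0.543 ± 0.0733 to 27.1 ± 1.99 FPKM (49.8-fold, n = 2, limma adjusted p = 0.000282).

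Super-enhancers were not mapped here. Genes near super-enhancers means the members of the list written from general knowledge of colon cancer cells, and they were not set against genes of like level. Of its 30 tested members, 21 fell, 2 rose and 7 did not pass the test. Adjusted over the list alone, 22 fell and 3 rose. The list was lower as a whole, with a median log2 change of -0.38 (camera adjusted p = 5.25e-09), and adjusted p = 0.209 with an estimated correlation. Besides F3, SOX4 and MYC, SOX9, a transcription factor of intestinal progenitors, fell from 33.6 ± 1.82 to 17.5 ± 0.371 FPKM (0.52-fold). The members that rose were IER3, an early response gene, 1.2-fold, and PLAUR, the urokinase receptor, 1.26-fold.

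WNT and beta-catenin targets fell in 5 of 7 tested members, also 5 when adjusted over the list alone (camera adjusted p = 2.01e-07, and adjusted p = 0.181 with an estimated correlation). They were SOX4, MYC, CCND1 (cyclin D), BMP4, a secreted signal that went from 67.7 ± 1.34 to 33 ± 0.531 FPKM, and DKK1, a secreted WNT antagonist that went from 261 ± 0.6 to 153 ± 3.07 FPKM. MYC, SOX4 and CCND1 are also in the super-enhancer list. Among 30 MYC targets of ribosome biogenesis, 29 had a log2 change below 0, 5 fell (9 when adjusted over the list alone) and the median was -0.14 (camera adjusted p = 3.24e-07, and adjusted p = 0.209 with an estimated correlation). MYBBP1A fell to 0.697 of control, WDR43 to 0.737, DDX18 to 0.83 and SLC19A1, the folate carrier, to 0.745, and NOP16 fell too. The HOX and stem cell list, known as ENL targets in leukemia, had 1 of 6 tested members that fell, HOXA11, from 2.59 ± 0.165 to 1.22 ± 0.292 FPKM (2 when adjusted over the list alone). HOXA10, HOXA13 and HOXA7 stood at 0.777, 0.626 and 0.897 of control without passing, although HOXA10 and HOXA13 passed on recovered reads (voom adjusted p = 0.00943 and 0.0209). Among members below the FPKM filter, HOXA9 fell on recovered reads (log2 change -0.30, voom adjusted p = 0.0219). CDK6, a kinase of the early cell cycle, rose from a mean of 1767 to 2415.5 reads (log2 change 0.46, voom adjusted p = 8.22e-08). That list's camera adjusted p was 0.00621, with adjusted p = 0.209 with an estimated correlation and 0.172 on recovered reads.

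Other large falls were those of PLAU, the urokinase protease (21.4 ± 0.194 to 7.75 ± 0.748 FPKM), FJX1 (0.259 of control), TRIB1, a pseudokinase (47.5 ± 1.07 to 21.6 ± 0.439 FPKM), TNS4, a focal adhesion protein (0.415), the nuclear receptor NR2F1 (0.399) and the transcription factor ZIC2 (0.431). MIR5702, a microRNA precursor, had the largest fall on this scale, from 6.77 ± 3.49 to 1.08 ± 0.522 FPKM. It rests on 6 and 13 reads in control against 2 and 1 with IAA, and its adjusted p of 0.0398 was 0.149 without IAA replicate 2 and 0.0546 with a pseudocount of 5.

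Aryl hydrocarbon receptor targets rose in 6 of 8 tested members and fell in 0, and 8 rose when adjusted over the list alone (median log2 change 0.79, camera adjusted p = 5.39e-08, and adjusted p = 0.181 with an estimated correlation). CYP1B1, which also oxidises foreign compounds, rose from 0.21 ± 0.0016 to 4.33 ± 0.0437 FPKM (20.6-fold), TIPARP, an ADP-ribosyltransferase that restrains the receptor, 2.85-fold, and STC2, a secreted glycoprotein, 2.18-fold. SLC7A5, an amino acid transporter, and NFE2L2, a regulator of the antioxidant response, rose 1.45-fold and 1.43-fold.

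The integrated stress response and unfolded protein list rose in 12 of 20 members and fell in 0 (15 rose when adjusted over the list alone, camera adjusted p = 8.49e-07, and adjusted p = 0.181 with an estimated correlation). Its central transcription factor ATF4 rose from 87.6 ± 3.05 to 122 ± 1.56 FPKM, its effector DDIT3 2.01-fold, HERPUD1, which serves degradation of misfolded proteins, 2.15-fold and the amino acid transporter subunit SLC3A2 1.45-fold. Immediate early genes rose in 16 of 34 members and fell in 4 (18 and 7 when adjusted over the list alone). FOS rose 2.9-fold, EGR1 2.35-fold, NR4A2 2.08-fold and BTG2, an antiproliferative gene, 1.48-fold, whereas MYC, PHLDA1, SPRY4 and KLF10 fell. The camera adjusted p of that list was 0.029, with adjusted p = 0.288 with an estimated correlation, and it was 0.0578 without IAA replicate 2. Among 21 p53 targets 5 rose and 0 fell (8 and 1 when adjusted over the list alone, camera adjusted p = 0.000525, and adjusted p = 0.257 with an estimated correlation). They were GDF15, a stress cytokine (1.74-fold), CDKN1A, an inhibitor of the cell cycle (30.7 ± 0.531 to 41.7 ± 0.122 FPKM), BTG2, TP53INP1 (1.54-fold) and XPC.

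The list on BET proteins and P-TEFb control had 4 of 7 tested members higher and 0 lower. Adjusted over the list alone, 5 rose and 1 fell. Its camera adjusted p was 0.0103, and 0.222 with an estimated correlation. SERTAD1 rose 2.19-fold, the BET protein BRD2 1.25-fold, and MEPCE and HEXIM1, parts of the complex that holds P-TEFb inactive, 1.34-fold and 1.18-fold (HEXIM1 41.8 ± 0.89 to 49.3 ± 0.804 FPKM). G2 and mitosis genes rose in 4 of 28 members and fell in 0 (9 rose when adjusted over the list alone, camera adjusted p = 0.00379, and adjusted p = 0.209 with an estimated correlation), with KIF20A, a mitotic kinesin, at 1.24-fold, HMMR at 1.33-fold, NUSAP1 at 1.21-fold and the mitotic kinase CDK1 at 1.15-fold, which did not pass with FPKM rescaled to TPM (0.0599). Other large rises were those of FAM43A (2.93-fold), BTG1, an antiproliferative gene (2.39-fold), and OVOL1, an epithelial transcription factor (2.45-fold).

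The remaining lists did not pass. ENL and its complexes had camera adjusted p = 0.702, with 1 of 13 members lower (DOT1L, the histone methyltransferase, 0.804 of control), and S phase genes had 0.702, with 1 of 28 lower (UHRF1). Cholesterol synthesis had 0.168, and hypoxia and glycolysis 0.448, with KDM3A higher and HK2 lower. Heat shock genes had 0.395, with BAG3, HSPA1B and DNAJB1 higher, NF-kB genes 0.702, with IRF1 higher, and interferon-stimulated genes 0.406, with STAT2 and IRF7 higher. YAP targets had 0.243, with GADD45A and AJUBA higher and F3, FJX1 and AXL lower, and adjusted p = 0.00648 on recovered reads. Cytosolic ribosomal proteins (0.498, and 0.0279 without control replicate 1) and the respiratory chain (0.584) had 0 changed members by limma.

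By limma, 1092 of 8317 genes changed between control and IAA, 552 up and 540 down, of which 131 changed at least 1.5-fold and 35 at least 2-fold on the log2(FPKM + 1) scale. With FPKM rescaled to TPM the split was 397 up and 647 down of 1044, 38.0% up in place of 50.5%. On recovered reads voom called 3531 genes, 2021 up and 1510 down (57.2% up). Without control replicates 1 and 2 the count was 71 and 57, without IAA replicates 1 and 2 it was 58 and 69, and without washout replicates 1 and 2 it was 535 and 538. Of the 44 named genes that changed, 19 kept an adjusted p under 0.05 without each of the 6 libraries, among them CYP1A1, F3, SOX4, MYC, TIPARP, FOS and SOX9. The other 25 reached between 0.0501 and 0.153 without 1 of them. Exons of CYP1B1, PLAU, BTG1, DDIT3, MEPCE, MYBBP1A, SLC19A1 and KIF20A overlap those of a neighbouring gene, and the strand counted is not given in the sources used here. HSPA1B is nearly identical to HSPA1A.

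**Figure D1:**
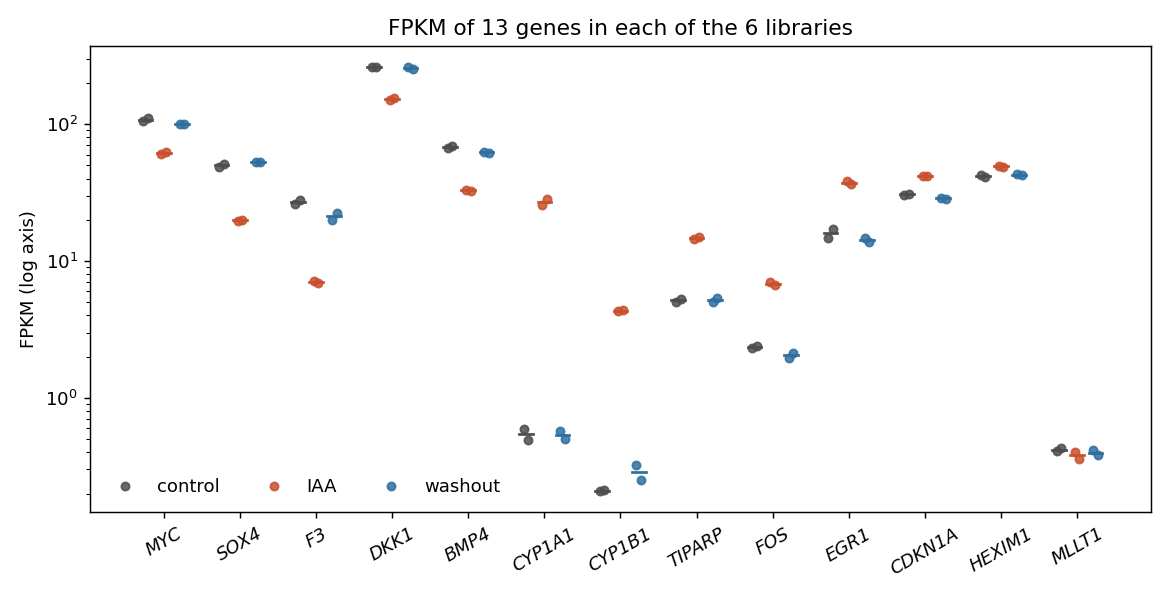
FPKM of 13 genes (horizontal axis) on a log axis (vertical), with 1 point per library of control, IAA and washout and a bar at each group's mean. CYP1A1 went from 0.543 to 27.1 FPKM with IAA and to 0.538 after washout, and MYC from 108 to 61.7 and 101 FPKM.

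The comparison of washout with IAA asked whether the changes are undone once IAA is removed. CYP1A1 fell from 27.1 ± 1.99 to 0.538 ± 0.0474 FPKM (SD, n = 2 per group, limma log2 change -4.19, SE 0.067, adjusted p = 0.00028). SOX4 rose 2.67-fold to 52.9 ± 0.521 FPKM (n = 2, limma adjusted p = 0.00183), MYC 1.63-fold to 101 ± 0.518 FPKM (n = 2, limma adjusted p = 0.00387) and F3 3.02-fold to 21.3 ± 1.65 FPKM (n = 2, limma adjusted p = 0.0028). FOS fell to 0.299 and EGR1 to 0.379 of their levels with IAA.

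Genes near super-enhancers rose in 19 of 30 members and fell in 5 (22 and 5 when adjusted over the list alone, camera adjusted p = 7.33e-07, and adjusted p = 0.236 with an estimated correlation). ZFP36L1, an mRNA decay factor, rose 1.8-fold, and the members that fell were IER3, PLAUR, LIF, VEGFA and ELF3. WNT targets rose in 5 of 7 members (6 when adjusted over the list alone, camera adjusted p = 9.43e-07, and adjusted p = 0.189 with an estimated correlation), with DKK1 1.68-fold and BMP4 1.89-fold higher. MYC targets of ribosome biogenesis rose in 6 of 30 (8 when adjusted over the list alone, camera adjusted p = 5.98e-05, and adjusted p = 0.236 with an estimated correlation), MYBBP1A 1.34-fold, WDR43 1.24-fold, DDX18 1.2-fold and SLC19A1 1.37-fold. In the HOX and stem cell list HOXA11 rose 2.35-fold, HOXA10 1.44-fold and HOXA7 1.26-fold, 3 of 6 members (4 when adjusted over the list alone, camera adjusted p = 0.00238). It had adjusted p = 0.209 with an estimated correlation and 0.216 on recovered reads, where HOXA7 did not pass (0.145), and HOXA13 stood at 1.76-fold without passing (0.072, and 0.00521 on recovered reads).

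Aryl hydrocarbon receptor targets fell in 7 of 8 members (7 when adjusted over the list alone, camera adjusted p = 2.56e-08, and adjusted p = 0.181 with an estimated correlation), CYP1B1 to 0.0662 and TIPARP to 0.353 of the level with IAA. The integrated stress response list fell in 12 of 20 (13 when adjusted over the list alone, camera adjusted p = 2.83e-07, and adjusted p = 0.181 with an estimated correlation), ATF4 to 0.647, HERPUD1 to 0.498 and CHAC1, a glutathione-degrading enzyme, to 0.364. Immediate early genes fell in 16 of 34, among them HBEGF, a growth factor (0.436), and rose in 5, MYC, SPRY4, PHLDA1, KLF10 and DUSP5 (17 and 7 when adjusted over the list alone, camera adjusted p = 0.00819, and adjusted p = 0.236 with an estimated correlation). Of the p53 targets 5 of 21 fell, GDF15 to 0.505, CDKN1A to 0.688, BTG2 to 0.625, TP53INP1 to 0.667, and TNFRSF10B (9 when adjusted over the list alone, camera adjusted p = 0.000122, and adjusted p = 0.236 with an estimated correlation). The list on BET proteins and P-TEFb control had 4 of 7 members lower, and 5 when adjusted over the list alone. Its camera adjusted p was 0.0149, and 0.233 with an estimated correlation. SERTAD1 fell to 0.513, BRD2 to 0.797, MEPCE to 0.781 and HEXIM1 to 0.863 of the level with IAA.

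S phase genes rose in 5 of 28 members after washout, UHRF1 1.42-fold, the replicative helicase subunits MCM5 1.23-fold and MCM6 1.16-fold, RFC4 1.19-fold, and CCNE1 (10 when adjusted over the list alone, camera adjusted p = 0.000122, and adjusted p = 0.209 with an estimated correlation). G2 and mitosis genes fell in 3 of 28, KIF20A to 0.78, HMMR to 0.765 and CDK1 to 0.872 (10 when adjusted over the list alone, camera adjusted p = 8.28e-05, and adjusted p = 0.181 with an estimated correlation), and CCNA2 stood at 0.838 without passing (0.0506, and 0.000367 on recovered reads). Interferon-stimulated genes rose in 4 of 12, IFIT1 2.07-fold, IFI27 1.72-fold, OAS3 1.26-fold and IFI35 1.21-fold, and STAT2 fell (7 and 1 when adjusted over the list alone, camera adjusted p = 0.00714, and adjusted p = 0.236 with an estimated correlation). On recovered reads IFI35 did not pass (0.0627). Heat shock genes fell in 4 of 17, HSPA1B to 0.654, BAG3 to 0.82, DNAJB1 to 0.867 and the chaperone HSP90AA1 to 0.893 (5 when adjusted over the list alone, camera adjusted p = 0.0226, and adjusted p = 0.476 with an estimated correlation), and the list had 0.124 without washout replicate 1. With FPKM rescaled to TPM, HSP90AA1 (0.0954), DNAJB1 (0.0612), CDK1 (0.0649) and HEXIM1 (0.0645) did not pass.

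The lists that did not pass were ENL and its complexes (camera adjusted p = 0.505, with DOT1L higher and CCNT1 and CCNT2 lower), cholesterol synthesis (0.0742, and 0.0411 without washout replicate 1, 1 higher and 4 lower), hypoxia and glycolysis (0.702, with a median of 0.0026 and a mean of -0.0426, 1 higher and 3 lower), NF-kB genes (0.702, IRF1 lower), YAP targets (0.267, 3 higher and 2 lower, and 0.00294 on recovered reads), cytosolic ribosomal proteins (0.215, RPL37 lower) and the respiratory chain (0.866, 0 changed by limma). Other large rises after washout were those of FJX1 (4.15-fold), PLAU (2.58-fold), TRIB1 (2.37-fold), TNS4 (2.36-fold), JMJD4 (2.82-fold), TIGD5 (2.28-fold), C10orf55 (2.62-fold) and CHST14, a sulfotransferase (2.19-fold). The exons of C10orf55 overlap those of PLAU, those of JMJD4 SNAP47, those of TIGD5 EEF1D, those of RFC4 EIF4A2, those of DNAJB1 TECR and those of HSP90AA1 WDR20. FAM43A fell to 0.38, BTG1 to 0.449, STC2 to 0.423 and OVOL1 to 0.462 of the level with IAA.

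By limma, 1196 of 8317 genes changed between IAA and washout, 643 up and 553 down. With FPKM rescaled to TPM 804 rose and 400 fell of 1204, 66.8% up in place of 53.8%. On recovered reads voom called 3697 genes, 1713 up and 1984 down (46.3% up). Without control replicates 1 and 2 the count was 427 and 413, without IAA replicates 1 and 2 it was 74 and 42, and without washout replicates 1 and 2 it was 70 and 97. Of the 58 named genes that changed, 19 kept an adjusted p under 0.05 without each of the 6 libraries, among them CYP1A1, SOX4, MYC, F3 and FOS. The other 39 reached between 0.051 and 0.169 without 1 of them.

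Of the 1092 genes that changed with IAA, 1015 (92.95%, Clopper-Pearson 95% interval 91.27% to 94.4%, counting error over genes only) had a washout mean nearer to control than to IAA. The median share of the IAA change that remained was 0.0716, with quartiles of -0.079 and 0.253. It was 0.108 and 0.0376 without control replicates 1 and 2, the range with a library left out. Simulated data with full recovery and the same selection rule gave 0.0434. Of the 552 genes that rose 393 fell again, and of the 540 that fell 432 rose again, 825 in all (75.5%), and 0 changed further in the same direction by limma. The number called back in the opposite direction was 69 of 71 and 57 of 57 without control replicates 1 and 2, 50 of 58 and 39 of 69 without IAA replicates 1 and 2, and 67 of 535 and 91 of 538 without washout replicates 1 and 2. It was 285 of 536 with only the 2 groups compared. Simulated data with the same selection rule gave 4.4% nearer to control with no recovery and 95.9% with full recovery. They took the observed group means as true and called a mean of 2128.3 genes with no recovery and 2108.4 with full recovery. The data had 1092 called genes, so the genes selected differ and the simulated values are only rough benchmarks. Both comparisons use the same IAA libraries, and simulated data with no recovery gave at most 1 gene called back.

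**Figure D2:**
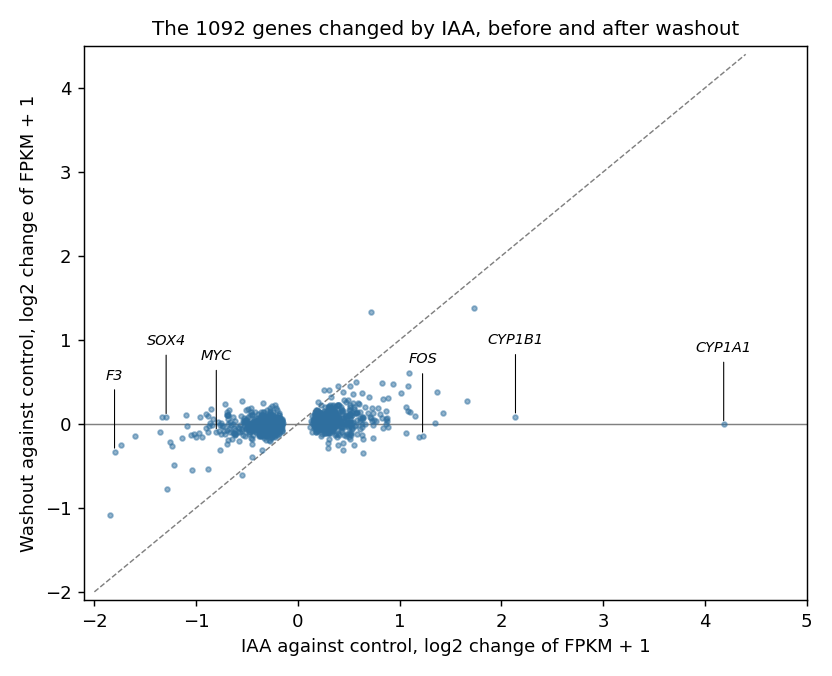
Log2 change in washout against control (vertical axis) over log2 change in IAA against control (horizontal axis), 1 point per gene that changed with IAA, with a dashed line where the whole change would remain and a horizontal line at 0. Of the 1092 genes, 1015 had a washout mean nearer to control than to IAA, and the median share of the change that remained was 0.0716, against 0.0434 in simulated data with full recovery.

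The comparison of washout with control asked what differs from untreated cells 48 h after IAA was removed. MYC stood at 101 ± 0.518 FPKM against 108 ± 2.69 in control (SD, n = 2 per group, limma adjusted p = 0.554), CYP1A1 at 0.538 ± 0.0474 against 0.543 ± 0.0733 (limma adjusted p = 0.99) and HEXIM1 at 42.5 ± 0.546 against 41.8 ± 0.89 (limma adjusted p = 0.865). F3 stood at 21.3 ± 1.65 against 27 ± 1.19 FPKM (0.787 of control, limma adjusted p = 0.507). The genes of smallest p were NUDT18, at 1.58 times control (limma adjusted p = 0.289), NAP1L5 (1.53), IFI35 (1.34), HES4, a Notch pathway repressor (1.33), and PRR24 (1.41) on the higher side. On the lower side were SNORD101 (0.647), CIB1 (0.838), NAA38 (0.818), EREG, a growth factor (0.815), and MTRNR2L8 (0.548). SNORD101 is a small nucleolar RNA that poly(A) selection captures poorly, and the exons of CIB1 overlap those of GDPGP1.

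Interferon-stimulated genes were higher as a list, with 11 of 12 members above control, a median log2 change of 0.25 and camera adjusted p = 2.56e-08 (adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone 9 were higher, and over all genes 0. IRF7, a regulator of interferon genes, stood at 1.51 times control, IFI27 at 1.66, OAS3, an antiviral enzyme, at 1.25 and IFI35 at 1.34. S phase genes were higher as a list too, with 28 of 28 members above control, a median of 0.11 and camera adjusted p = 1.63e-09 (adjusted p = 0.181 with an estimated correlation). Adjusted over the list alone and over all genes 0 of them changed by limma, and MCM5 stood at 1.17 times control, RFC4 at 1.15, the thymidine kinase TK1 at 1.12 and MCM4 at 1.11.

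Genes near super-enhancers were slightly lower as a list, with a median of -0.05, 0 changed members and 0 when adjusted over the list alone (camera adjusted p = 0.000752, adjusted p = 0.372 with an estimated correlation, and 0.0696 without control replicate 2). F3 (0.787 of control), PHLDA1 (0.88), VEGFA (0.83) and the cytokine LIF (0.908) stood below control. Another 4 lists had camera adjusted p under 0.05 that was lost without some library, with 0 members changed by limma over all genes and adjusted over the list alone. MYC targets of ribosome biogenesis (median -0.02, 0.0394, and adjusted p = 0.482 with an estimated correlation) had 0.482 without control replicate 2, 0.0577 and 0.0567 without IAA replicates 1 and 2, and 0.159 and 0.0762 without washout replicates 1 and 2. With the replicate block that list had camera adjusted p = 0.0741. Among its members WDR43 stood at 0.914 and GNL3 at 0.917 of control, and CDK4 at 1.08. Immediate early genes (median -0.02, 0.0322, and adjusted p = 0.289 with an estimated correlation) had 0.172 without control replicate 2, 0.0558 and 0.0549 without IAA replicates 1 and 2, 0.152 without washout replicate 2 and 0.0565 with quantile normalization. FOS stood at 0.868, EREG at 0.815 and NR4A2 at 1.21 times control.

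Hypoxia and glycolysis genes (median -0.06, 0.0159, and adjusted p = 0.519 with an estimated correlation) had 0.106 without control replicate 2 and 0.901 without washout replicate 1, where the median lay just above 0. There VEGFA, DDIT4, an inhibitor of growth signalling (0.796), NDRG1 (0.843) and the hexokinase HK2 (0.871) stood below control. Heat shock genes (median -0.04, 0.0159, and adjusted p = 0.467 with an estimated correlation) had 0.22 without control replicate 2 and 0.372 without washout replicate 1, with HSP90AA1 at 0.906, CHORDC1 at 0.826, HSPH1 at 0.913 and HSPA1B at 0.929 of control. The list on BET proteins and P-TEFb control did not pass (camera adjusted p = 0.369). SERTAD1 stood at 1.12, LARP7 at 1.06 and MEPCE at 1.05 times control.

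G2 and mitosis genes did not pass (0.0592, but 0.0357 with median centring and 0.0152 on recovered reads). The other lists that did not pass were ENL and its complexes (0.403), WNT targets (0.157), HOX and stem cell genes (0.155, and 0.023 without washout replicate 2), aryl hydrocarbon receptor targets (0.353), p53 targets (0.172), cholesterol synthesis (0.516), the integrated stress response (0.18), NF-kB genes (0.707), cytosolic ribosomal proteins (0.445, and 0.00381 without control replicate 2) and the respiratory chain (0.198, and 0.00296 without control replicate 1). YAP targets had 0.968, with a median of 0.0326 and a mean of -0.000841.

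By limma, 0 of 8317 genes changed between washout and control, where the smallest adjusted p was 0.23 and 750 genes had an unadjusted p under 0.05. With no filter on low values limma called 48. On recovered reads voom called 94, 45 up and 49 down, among them OAS3, IFI27, MCM5 and HES4 on the higher side and F3, EREG, VEGFA, PHLDA1, HSP90AA1 and CHORDC1 on the lower, with log2 changes of -0.35 for F3 (adjusted p = 4.21e-05) and 0.32 for OAS3 (adjusted p = 0.000416). In simulated libraries limma called 66% of genes changed 1.5-fold and 18% of those changed 1.25-fold in IAA against control, so limma on FPKM can miss single genes with differences of this size. Voom on reads called 88% and 72% of such genes. These simulated genes shared 1 dispersion, so the shares are rough and do not settle why voom called 94 genes and limma 0.

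**Figure D3:**
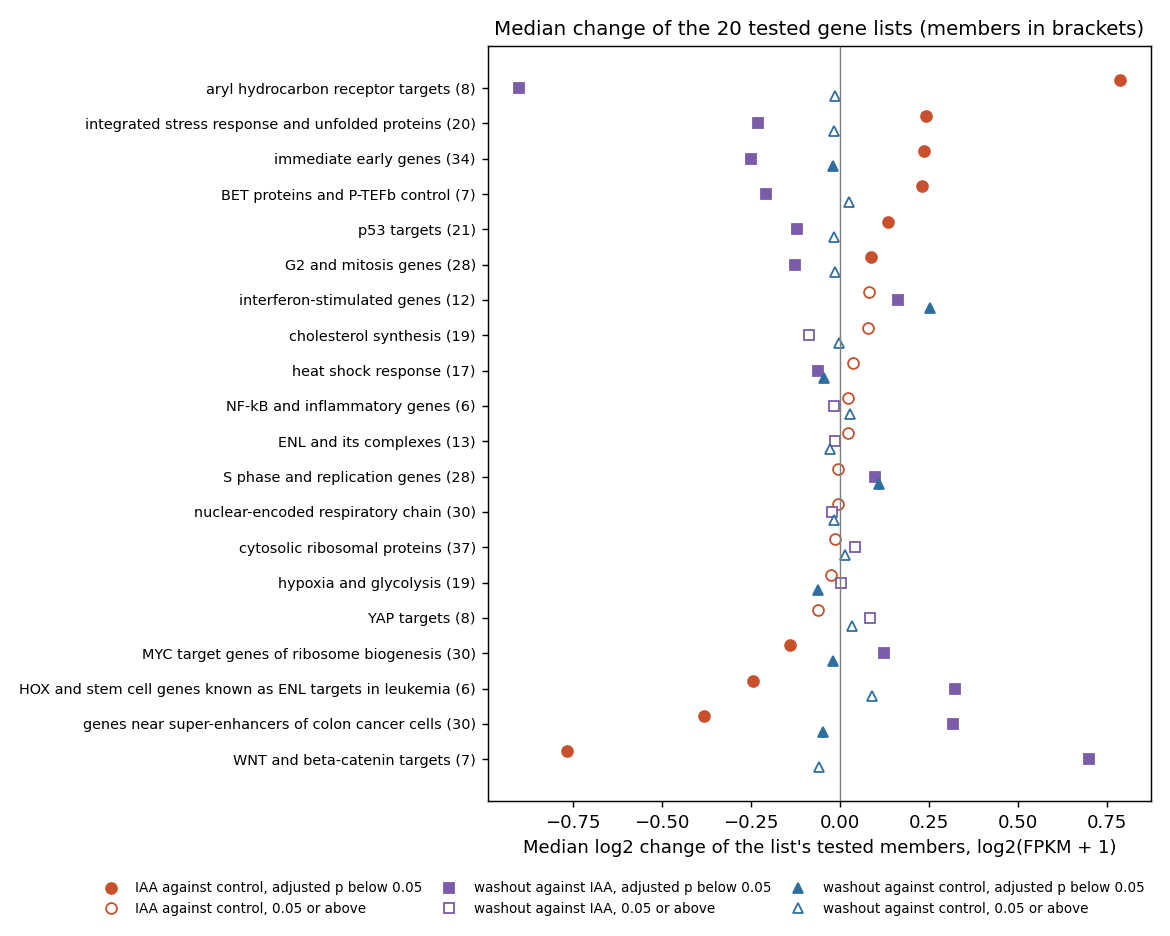
Median log2 change of each tested gene list in IAA against control, washout against IAA and washout against control, 1 point per list and comparison, filled where the camera adjusted p was under 0.05. Genes near super-enhancers had a median of -0.38 with IAA and of -0.05 after washout against control, and aryl hydrocarbon receptor targets 0.79 with IAA.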

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

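The tests on recovered reads and on protein-coding genes alone were chosen after seeing the data. No called result passed its threshold in the opposite direction under any alternative. Of the alternatives' results for single named genes, 2817 stayed on their side of the threshold, 454 lost and 56 gained a call and 6 moved. For lists the counts were 709, 54 and 17. Of 102 called results for named genes, 66 were lost with a log2 limit of 1, 58 and 58 without IAA replicates 1 and 2, 44 and 45 without control replicates, 42 and 39 without washout replicates, 31 with only the groups compared, 27 with the replicate block, 21 with no filter, and 0 to 5 with each other setting. Changed genes with IAA (1092) and after washout against IAA (1196) numbered 501 and 548 with FPKM of at least 5 (fewer genes tested), 536 and 413 with only the groups compared and 57 to 538 and 42 to 427 with a library left out (fewer samples), and 35 and 23 with a log2 limit of 1. Replicate deviations were hardly correlated between groups (0.043 for control and IAA, -0.027 for control and washout, 0.006 for IAA and washout). No pairing by replicate number was seen, but a weak one is not excluded. A replicate block gave 486, 532 and 0 in the 3 comparisons, with 1 residual degree of freedom fewer. Voom on reads gave 3531 and 3697, log2 scaled reads 3568 and 3721, and voom on genes of the FPKM test 2318 and 2422. Voom called 1026 of the 1092 genes again. Protein-coding genes alone gave 1662 with IAA. In washout against control (0) the counts were 28 with FPKM of at least 0.1, 48 with no filter, 0 to 1 with a library left out (1 without IAA replicate 1), 94 with voom on reads, 79 with log2 scaled reads and 79 with voom on genes of the FPKM test. The share nearer to control (92.95%) was 85.71% with a log2 limit of 1, 88.66% to 98.55% with a library left out, 87.65%, 87.72% and 87.32% in these tests on reads, and 89.59% for protein-coding genes. With an estimated correlation, which leaves little power at 3 residual degrees of freedom, 0, 0 and 0 lists passed in the comparisons. In washout against control 7 lists passed, 4 to 8 with a library left out (4 without control replicate 2 and without washout replicate 1), and 2 with fry. Where no reason is given the cause was not tested. In simulated data limma on FPKM called 18% of genes changed 1.25-fold and 66% of those changed 1.5-fold. Voom on reads called 72% and 88%, and the false calls were 14 and 8. The simulated genes shared 1 dispersion, so these values are rough.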

Other observations

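The tests on recovered reads, of IAA apart from ENL and of time in culture were chosen only after the result was seen, as was the use of median centring and of left-out libraries, both planned settings, to test the patterns here, and the genes here were picked after their values were seen.

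Of the genes with enough reads, 6732 lay below the FPKM filter, and voom on their recovered reads called 1307 with IAA, 878 up and 429 down. PDE4B, which degrades cyclic AMP, fell from a mean of 2090 to 692.5 reads and stood at 2175.5 after washout (n = 2, log2 change -1.59, SE 0.08, voom adjusted p = 1.48e-17). NR5A2, a nuclear receptor, fell from 1133.5 to 325.5 reads (log2 change -1.79), BDNF, a growth factor, from 1466.5 to 502 (-1.54), the integrin ITGB8 from 956 to 345.5 (-1.46), and CYP24A1, which inactivates vitamin D, from 148 to 35.5 (-2.04). AHRR, the repressor of the aryl hydrocarbon receptor and a target of it, rose from 486.5 to 1699.5 reads (log2 change 1.82, voom adjusted p = 1.19e-16) and stood at 544.5 after washout. SASH1 rose from 218.5 to 988 reads, FAM46C from 71.5 to 346, FOSB, an immediate early gene, from 46 to 193, and ATF3, a stress-induced transcription factor, from 207.5 to 532.5. The WNT feedback genes AXIN2 and RNF43 fell (log2 changes -0.81 and -0.77), whereas EPHB3, also in the WNT list, rose (0.97).

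Keratins, which form the filaments of epithelial cells, were in part lower with IAA on recovered reads. Of 14 protein-coding keratin genes 8 fell with IAA, 6 did not pass the test and 0 rose by voom, among them KRT80 from 2449.5 to 1156 reads (n = 2, log2 change -1.08, voom adjusted p = 5.44e-16) and KRT8, KRT18 and KRT19 (log2 changes -0.32, -0.38 and -0.32). After washout 9 rose against IAA and 0 fell. KRT81 also fell (-1.25), but it shares sequence with KRT86 and pseudogenes, so its reads are uncertain. Keratins were not a list fixed beforehand. After washout, voom called KITLG, a growth factor, lower than control (log2 change -0.25, adjusted p = 8.59e-07) and the interferon-stimulated gene ISG15 (0.3, adjusted p = 5.08e-05) higher.

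Aryl hydrocarbon receptor targets were higher with IAA at camera's preset correlation. They had camera adjusted p = 0.181 with an estimated correlation, where no list passed, and fry adjusted p = 2.92e-05. Centring libraries on their median left the list's median log2 change at 0.776, which argues against library scaling. Without CYP1A1 and CYP1B1 the other 6 members had a camera p of 7.76e-06 at the preset correlation and a median log2 change of 0.42, which argues against these genes alone carrying the list. IAA is an indole, a class that holds ligands of this receptor, so IAA acting on the receptor apart from the loss of ENL is a candidate explanation. There were 0 libraries with IAA and no degron, so this and an effect of ENL cannot be told apart, and the same holds for any other change with IAA.

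Interferon-stimulated and S phase genes were higher as lists after washout than in control at camera's preset correlation. With an estimated correlation neither list passed (camera adjusted p = 0.181 for both), but no list passed that test, which has little power here. With fry the adjusted p was 0.00568 for interferon-stimulated and 0.00649 for S phase genes. The highest camera adjusted p with a library left out was 3.55e-06 and 2.98e-07, which argues against a single library as the cause, and with median centring the medians were 0.241 and 0.0974, which argues against library scaling. The washout cells were cultured for 48 h after the wash, and the labels do not say how long control cells were grown. Of the control libraries 0 are described as grown for the washout time. The washout cells also had IAA and a PBS wash. Time in culture, IAA itself, the wash and a lasting effect of ENL loss therefore cannot be told apart. The rise may reflect any of them.

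Changes with IAA could follow gene span, since long genes take longer to transcribe. Across 12543 protein-coding genes, which are not independent replicates, Spearman's rho between log2 change on reads and gene span was 0.034, against -0.13, 0.022 and 0.063 between the replicates of control, IAA and washout. In 4 nearly equal groups of genes by span, voom called 400 up and 351 down in the shortest (median 7.18 kb). The next groups had 455 up and 360 down, and 518 up and 336 down. The longest (median 140 kb) had 485 up and 334 down. A rho this near 0, and within the range between replicates, argues against span setting the direction of change across all these genes. Most of them were not called. Among called genes rises outnumbered falls by more in the longer groups, and whether span bears on that was not tested. Since changes went both ways, a rho of signed changes cannot tell whether span limits their size, which was not tested.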
